A study of Rattus norvegicus with 15 samples.

How the data were processed

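The data are 15 one-colour Agilent rat arrays, 1 per RNA sample, from primary hepatocytes of male Wistar rats, bought frozen according to the labels' protocols. After 24 h of pre-culture the cells had been exposed for 24 h to DMSO or to 30 µM of naphthalene, 1-naphthol or a diol (1,5- or 2,7-naphthalenediol), with 3 arrays per group. Per the labels' protocols, RNA was extracted with the miRNeasy kit and 100 ng was labelled with Cy3 by the Low Input Quick Amp kit. The deposited files hold 1 intensity per spot, made by the authors with Feature Extraction 10.7.1.1, and per the file headers this intensity had its background subtracted and was detrended within the array, but was not normalized between arrays. The file headers place the arrays on 2 slides. The dose and time were matched for all 4 compounds. The age of the donors and the time between the experiments are not given in the sources used here.

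Each array held 58717 gene spots and 4259 control spots. Control spots and spots that the deposited files mark as non-uniform or as population outliers (250 to 354 per array) were left out, and no gene spot was saturated. Intensities were put on the log2 scale, the array's own 75th percentile was subtracted, and spots of 1 probe were averaged. Of 45598 gene probes, 21229 matched 1 symbol through their transcript accession in the gene table given as reference, of assembly GRCr8, covering 16678 symbols, and 24369 kept their accession. The file headers name the older build rn4, so no coordinates are given. A probe was kept when it was well above background on all 3 arrays of at least 1 group, which 23562 probes met. Of these, 7 with a missing value were left out. For a gene with more than 1 such probe (3018 genes) the brightest was used, which left 19803 genes to test, 10503 with a symbol and 9300 under an accession. Genes without a probe of their name among those kept were not analysed here.

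Signal over background sets the depth of these arrays: 57.4% to 61% of gene spots were well above background, and the 75th percentile lay at 1718 to 2074 intensity units. The lowest correlation between 2 arrays of a group was 0.996, and the smallest standard deviation of the log2 difference between 2 such arrays was 0.181. Where the lower group of a comparison was not well above background on all of its arrays, the fold is given as a lower bound. For it each array of that group counted with the higher of its own signal and the lowest signal well above background on that array. This bound allows for dim signal only. It equals the measured fold where the group's own signals were the higher, and the spread between arrays can reach below it.

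Groups were compared in limma 3.58.1 (R 4.3.3, with version 1.17.8 of data.table) with 1 model of the 5 group means over all 15 arrays, moderated statistics and Benjamini-Hochberg adjusted p below 0.05 within each comparison. There were 10 comparisons, the 4 compounds against DMSO and the 6 pairs of compounds, and a moderated F test of any difference. Confidence intervals are at 95%. Rose, fell, higher and lower are used of genes past the threshold, and values are given otherwise. The replicate numbers do not pair the samples, since 2 of 30 same-number pairs of arrays correlated above 0.1 after the group means were removed and 5 of 15 arrays correlated best with their own number. The slide entered as a fixed block in an alternative model given beside the results. In that model 1-naphthol and naphthalene are compared with DMSO through the 2 arrays of 1,5-naphthalenediol on slide 1 and the 1 on slide 2, which widens the errors.

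Gene lists were tested with camera in limma against all other genes, with its preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists of a comparison. The alternatives were camera with a correlation estimated from the data and fry. In all, 25 lists were written before the data were examined, as were the comparisons, the key genes and the rule for naming genes. They cover NRF2 targets with redox and glutathione genes, AhR targets, CAR and PXR targets, PPAR-alpha targets with fatty acid oxidation, p53 targets, ER chaperones and the unfolded protein response, the ATF4 and amino acid response, the heat shock response, the metal response, proteasome subunits, phase II conjugation, cholesterol synthesis, fatty acid and triglyceride synthesis, bile acid synthesis and transport, hepatocyte function, acute phase and inflammation, cell cycle, hypoxia and glycolysis, oxidative phosphorylation, immediate early genes, and markers of stellate cells, macrophages, endothelial cells, bile duct cells and lymphocytes. Lists with fewer than 5 tested genes were not tested, which left 24. Some genes belong to more than 1 list. A list of 50 interferon-stimulated genes, 43 of them tested, was written after single genes had been seen.

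The naming rule took 24 key genes for every compound, 19 of which were tested: Nqo1, Hmox1, Gclc, Txnrd1, Srxn1, Cyp1a1, Cyp1a2, Cyp3a23-3a1, Cyp4a1, Mt1, Cdkn1a, Mdm2, Gdf15, Ddit3, Atf3, Trib3, Hspa1a, Alb and Cyp2e1. The other 5 were Gclm, Cyp1b1 and Cyp7a1, whose probes did not pass the filter, and Tiparp and Cyp2b1, which had no named probe. It further took, among genes past the threshold whose arrays did not overlap between the groups, the 8 largest rises and the 8 largest falls against DMSO, 5 of each between compounds, and for each list up to 2 genes with the lowest adjusted p in each direction. The text names part of these, chosen after their values were seen. Genes reported as shared by the hydroxylated compounds were also chosen after their values were seen.

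Profiles of the compounds against DMSO were compared by Pearson correlation, covariance and overlap of calls. Simulation of 100 sets of unchanged groups against 3 shared controls gave the values to set beside them, and 100 further sets held a slide difference (standard deviation 0.191), fitted without and with the slide block. Alternatives were the normexp background correction (offset 50, on the median spot and background intensity, since the deposited files give no mean intensity), quantile normalization, no filter on dim probes, a filter requiring all 15 arrays, the mean of a gene's probes, moderation with trend and robust settings, only the arrays of the groups compared, a block for replicate number, the slide as a fixed or a random block, slide and replicate blocks together, the arrays of 1 slide, and leaving out each array. The results were also set against other splits of the same arrays into groups, for the F test also within each slide. The pipeline was tested on simulated data for 1-naphthol against DMSO with 200 changed genes of 19803. It recovered 68%, 92% and 98% of genes changed by 0.5, 1 and 2 on the log2 scale with 8 false calls. With a simulated slide difference (standard deviation 0.191) there were 5430 false calls without the slide block and 7 with it, which recovered 30%, 72% and 88%. In 20 simulated runs a shifted NRF2 list was found 20 times, with 0 false calls in 340 list tests. The simulated genes varied independently, so these runs cannot show false calls of lists whose genes vary together.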

Results

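The 4 compounds and the solvent DMSO were compared in primary hepatocytes of male Wistar rats, at 30 µM for 24 h and with 3 arrays per group. The question was which expression changes naphthalene shares with its hydroxylated analogs 1-naphthol, 1,5-naphthalenediol and 2,7-naphthalenediol, as read-across of liver toxicity between them requires. Of 19803 genes tested, 8852 (44.7%) differed among the 5 groups in limma's F test at a Benjamini-Hochberg adjusted p below 0.05. All p-values use the spread between arrays, which the design text describes as independent experiments. Slide 1 held the 3 DMSO arrays, the 3 arrays of 2,7-naphthalenediol and 2 of 1,5-naphthalenediol. Slide 2 held the remaining array of 1,5-naphthalenediol and all arrays of 1-naphthol and naphthalene. No slide holds both DMSO and 1-naphthol or naphthalene, so for these comparisons slide and compound cannot be told apart except through 1,5-naphthalenediol. With the slide as a block in the model, 5196 genes (26.2%) differed among the groups. Below, changes are log2 changes ± standard error.

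Exposure to 2,7-naphthalenediol, which carries a hydroxyl group on each ring, raised the aldehyde dehydrogenase gene Aldh3a1. This gene, a classical target of the aryl hydrocarbon receptor (AhR), rose at least 4.27-fold (measured change 2.09 ± 0.105, adjusted p = 3.07e-06). Cyp1a1, which oxidises aromatic compounds, rose by 0.61 ± 0.121 (adjusted p = 0.011). The quinone reductase Nqo1 rose by 0.41 ± 0.0595 (adjusted p = 0.00326) and the heme oxygenase Hmox1 by 0.42 ± 0.0687 (adjusted p = 0.00488). Slc7a11, which imports cystine for glutathione synthesis, rose by 0.61 ± 0.0786 (adjusted p = 0.00192), and the glutathione transferase Gstp1 by 0.35 ± 0.0423 (adjusted p = 0.00136). The stress cytokine Gdf15 rose by 0.79 ± 0.119 (adjusted p = 0.00359). The immediate early transcription factor Egr1 rose by 1.38 ± 0.154 and the corepressor Ctbp2 at least 2.71-fold (measured change 1.44 ± 0.264; adjusted p = 0.000985 and 0.00777). Interferon-responsive genes lay lower than in DMSO: the antiviral GTPase Mx1 by -1.93 ± 0.457, the chemokine Cxcl11 by -1.10 ± 0.218 and the death ligand Tnfsf10 at least 2.46-fold (-1.30 ± 0.272; adjusted p = 0.0225, 0.0115 and 0.0139). The Mx1 call ended without DMSO 2 (adjusted p = 0.069), DMSO 3 (0.0818), 2,7-naphthalenediol 2 (0.0817) or 2,7-naphthalenediol 3 (0.0703) and on slide 1 alone (0.0575). The Tnfsf10 call ended without DMSO 3 (adjusted p = 0.0552). The DMSO arrays themselves differed here: the mean of 43 interferon-stimulated genes, relative to all 15 arrays, was 1.1 and 0.93 on DMSO 2 and 3 but 0.31 on DMSO 1.

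Among the fixed gene lists, 7 of 24 were called with 2,7-naphthalenediol, 5 upward and 2 downward, and 0 remained with an estimated correlation between genes. Of 39 NRF2 targets and redox genes, 13 rose and 0 fell (15 and 1 adjusted over the list alone), with a list test at adjusted p = 2.93e-05 and adjusted p = 0.218 with an estimated correlation. Of 9 AhR targets, 5 rose and 0 fell (5 and 1 over the list alone; adjusted p = 0.00347, and adjusted p = 0.218 with an estimated correlation). The list of 25 chaperones of the endoplasmic reticulum (ER) had 7 genes up and 0 down (8 and 1 over the list alone; adjusted p = 0.0029, and adjusted p = 0.413 with an estimated correlation). Its examples were Syvn1, a ubiquitin ligase for misfolded proteins, at 0.44 ± 0.0427 and the chaperone Dnajb9 at 0.24 ± 0.0349. The cholesterol synthesis list was called downward, with 1 of 25 genes up and 10 down (2 and 13 over the list alone; adjusted p = 0.00111, and adjusted p = 0.413 with an estimated correlation). Acat2 and Fdps, enzymes of its early steps, fell by 0.35 ± 0.0412 and 0.29 ± 0.0405. Among 43 oxidative phosphorylation genes 0 rose and 5 fell (0 and 10 over the list alone; adjusted p = 2.29e-06, and adjusted p = 0.413 with an estimated correlation). The list of immediate early genes was called upward, 8 of 21 up and 1 down (12 and 1 over the list alone; adjusted p = 2.29e-06, and adjusted p = 0.218 with an estimated correlation). The proto-oncogene Myc rose by 0.27 ± 0.0395, and outside this list the chemokine Cxcl1 rose by 0.52 ± 0.0761 and the cytokine signal inhibitor Socs3 by 0.45 ± 0.0457. The cell cycle list was also called upward, with 5 of 27 genes up and 0 down (7 and 0 over the list alone; adjusted p = 0.00111, and adjusted p = 0.413 with an estimated correlation), among them the ribonucleotide reductase subunit Rrm2 at 0.59 ± 0.12.

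Of the 19 key genes tested, 7 rose with 2,7-naphthalenediol, 0 fell and 12 did not pass, with changes of -0.11 to 0.23. The 7 were Nqo1, Hmox1, Cyp1a1, Gdf15, Cyp1a2 (0.25 ± 0.0631), Srxn1 (0.27 ± 0.0799) and Txnrd1 (0.26 ± 0.0746). The calls of Cyp1a2, the sulfiredoxin Srxn1 and the thioredoxin reductase Txnrd1 ended when any 1 of the 6 arrays was left out, with adjusted p up to 0.0841 (without 2,7-naphthalenediol 3), 0.159 (without 2,7-naphthalenediol 3) and 0.149 (without 2,7-naphthalenediol 3). In all, 1228 genes rose and 958 fell (55 by 2-fold or more), 2184 of these 2186 also with the slide block, which alters only errors here and called 2990. Slide 1 alone called 1853 genes, 1431 of them shared. When 1 array was left out, 732 genes (without 2,7-naphthalenediol 2) to 1614 (without 2,7-naphthalenediol 1) were called.

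With 1,5-naphthalenediol, whose hydroxyl groups also sit on different rings, Aldh3a1, Cyp1a1, Nqo1 and Gstp1 were higher than with 2,7-naphthalenediol, and Hmox1 was not. Against DMSO Aldh3a1 rose at least 12-fold (3.58 ± 0.105, adjusted p = 9.04e-10), Cyp1a1 by 2.22 ± 0.121 (adjusted p = 3.97e-07) and Nqo1 by 1.63 ± 0.0595 (adjusted p = 8.76e-09). Gstp1 rose by 2.29 ± 0.0423 (adjusted p = 1.61e-11), the aldo-keto reductase Akr1b8 by 1.70 ± 0.0474 (adjusted p = 5.82e-10) and the glutathione transferase Gsta2 by 1.19 ± 0.0714 (adjusted p = 8.8e-07). The small heat shock protein Hspb1 rose by 2.62 ± 0.0996 (adjusted p = 1.24e-08). Genes close to background in DMSO also rose: the microtubule-associated Cimap2 at least 8.8-fold, the actin-binding Coro1a at least 5.44-fold and Prkar2b, a regulatory subunit of protein kinase A, at least 4.51-fold. Their measured changes were 3.69 ± 0.271, 2.84 ± 0.348 and 2.47 ± 0.519 (adjusted p = 4.88e-06, 0.000188 and 0.00562). The cytokine-like gene Cytl1 fell at least 3.99-fold (-2.37 ± 0.298, adjusted p = 0.000224). The muscle-type genes Myl2 and Mybpc3 fell by 1.80 ± 0.149 and at least 3.45-fold (adjusted p = 1.23e-05 and 0.000176), and Mx1 by 2.40 ± 0.457 (adjusted p = 0.00324). Socs3 rose by 0.89 ± 0.0457, and Alas1, which starts heme synthesis, by 0.95 ± 0.0653.

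Fixed lists called with 1,5-naphthalenediol numbered 14, 8 upward and 6 downward, and 1 remained with an estimated correlation. That list was the NRF2 targets, with 17 genes up and 2 down (26 and 2 over the list alone; adjusted p = 1.69e-12, and adjusted p = 0.027 with an estimated correlation). AhR targets went both ways, 4 up and 2 down (5 and 2 over the list alone; adjusted p = 0.000361, and adjusted p = 0.0796 with an estimated correlation). Cyp2s1 fell by 0.21 ± 0.0482, and Ugt1a6 by 0.12 ± 0.0377 on its brightest probe, but Ugt1a6 rose by 0.26 (adjusted p = 0.00323) on the mean of its probes. The fall of Ugt1a6 also ended without DMSO 1 (adjusted p = 0.0707), DMSO 2 (0.0713), DMSO 3 (0.106) or 1,5-naphthalenediol 1 (0.115). The list of targets of the xenobiotic receptors CAR and PXR had 13 of 24 up and 1 down (15 and 1 over the list alone; adjusted p = 7.58e-07, and adjusted p = 0.129 with an estimated correlation), Alas1 among them. The phase II conjugation list had 14 of 46 genes up and 5 down (17 and 6 over the list alone; adjusted p = 0.02, and adjusted p = 0.439 with an estimated correlation), and its call ended without 1,5-naphthalenediol 2 (adjusted p = 0.0548).

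Among further lists called upward with 1,5-naphthalenediol, heat shock genes split 10 up and 3 down of 19 (13 and 3 over the list alone; adjusted p = 0.000122, and adjusted p = 0.129 with an estimated correlation): the cochaperone Fkbp4 rose by 0.36 ± 0.0425 while the chaperone Hspa8 fell by 0.31 ± 0.0316. Proteasome subunits had 9 of 32 up and 1 down (14 and 2 over the list alone; adjusted p = 0.000287, and adjusted p = 0.255 with an estimated correlation), with Psmb3 at 0.33 ± 0.048 and Psmd3 at 0.36 ± 0.0574. Metal response genes had 5 of 9 up and 0 down (6 and 3 over the list alone; adjusted p = 0.0113, and adjusted p = 0.256 with an estimated correlation). The metallothioneins Mt1 and Mt2A rose by 0.24 ± 0.0387 and 0.32 ± 0.0428, and the transferrin receptor Tfrc by 0.46 ± 0.0526. Cell cycle genes had 13 of 27 up and 2 down (13 and 3 over the list alone; adjusted p = 0.000137, and adjusted p = 0.256 with an estimated correlation), with the replication licensing factors Mcm2 and Mcm3 at 0.39 ± 0.0447 and 0.56 ± 0.0644.

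Of the 6 lists called downward with 1,5-naphthalenediol, cholesterol synthesis had 1 of 25 genes up and 15 down (1 and 16 over the list alone; adjusted p = 2.69e-07, and adjusted p = 0.143 with an estimated correlation). Fdps and Hmgcs1 fell by 0.60 ± 0.0405 and 0.54 ± 0.0485. Fatty acid and triglyceride synthesis had 4 of 28 up and 11 down (4 and 14 over the list alone; adjusted p = 0.015, and adjusted p = 0.439 with an estimated correlation). Acly and Acss2, which supply acetyl-CoA, each fell by 0.59 (± 0.0621 and 0.0555). Targets of the lipid receptor PPAR-alpha had 5 of 36 up and 17 down (6 and 19 over the list alone; adjusted p = 0.00441, and adjusted p = 0.256 with an estimated correlation). The hormone Fgf21 and the lipase inhibitor Angptl4 fell by 0.49 ± 0.0619 and 0.50 ± 0.0706, whereas Ppara itself rose by 0.73 ± 0.0759 and Cpt1a by 0.40 ± 0.06. The amino acid response driven by ATF4 had 2 of 33 up and 16 down (4 and 16 over the list alone; adjusted p = 0.000982, and adjusted p = 0.272 with an estimated correlation). Its asparagine synthetase Asns and stress regulator Nupr1 fell by 0.32 ± 0.0335 and 0.54 ± 0.0588, while Cebpb rose by 0.28 ± 0.0441. Hypoxia and glycolysis genes had 1 of 22 up and 8 down (1 and 9 over the list alone; adjusted p = 0.02, and adjusted p = 0.191 with an estimated correlation), with P4ha2 and Pdk1 at -0.33 ± 0.0388 and -0.29 ± 0.0412. Without 1,5-naphthalenediol 3 the hypoxia and fatty acid synthesis lists lost their calls (adjusted p = 0.0612 and 0.109). The slide block is the same fit here and gives the same values. Oxidative phosphorylation had 1 of 43 up and 10 down (1 and 15 over the list alone; adjusted p = 0.000122, and adjusted p = 0.329 with an estimated correlation), with the succinate dehydrogenase subunits Sdha and Sdhb at -0.20 ± 0.0363 and -0.22 ± 0.0383.

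Among the 19 key genes tested with 1,5-naphthalenediol, 4 rose (Nqo1, Cyp1a1, Mt1 and Cyp4a1), Atf3 fell by 0.43 ± 0.0823 and 14 did not pass, with changes of -0.15 to 0.34. Hmox1 was at 0.17 (95% confidence interval 0.02 to 0.32, adjusted p = 0.105). Cyp4a1, at 0.13 (adjusted p = 0.0498), lost its call without DMSO 1 (0.0543), DMSO 2 (0.117), DMSO 3 (0.152), 1,5-naphthalenediol 2 (0.132) or 1,5-naphthalenediol 3 (0.142, the same fit as the slide block). In all, 1863 genes rose and 2523 fell (167 by 2-fold or more). The slide block called 4381 genes, 3517 of them shared in direction, and slide 1 alone called 3554, with 2902 shared.

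1-Naphthol, which carries a single hydroxyl group, raised Aldh3a1 further than the diols did. Against DMSO it rose at least 19.0-fold (4.25 ± 0.105, adjusted p = 7.1e-10), Cyp1a1 by 2.39 ± 0.121 (adjusted p = 5.24e-07) and Nqo1 by 1.24 ± 0.0595 (adjusted p = 3.57e-07). Gstp1 rose by 0.92 ± 0.0423 (adjusted p = 3.31e-07), Gsta2 by 0.83 ± 0.0714 (adjusted p = 8.51e-05) and the cytochrome P450 Cyp2b3 by 0.65 ± 0.0484 (adjusted p = 2.18e-05). The nucleobase transporter gene Slc43a3 rose by 1.62 ± 0.145 (adjusted p = 0.000115). All 7 of these calls held with the slide block, at 4.54, 2.21, 1.19, 0.96, 0.69, 0.57 and 1.93 (adjusted p = 4.2e-07, 0.00139, 0.00103, 0.000622, 0.0307, 0.0164 and 0.00752). Dim genes rose as well: Cimap2 at least 2.9-fold, the membrane protein gene Tmem117 at least 3.81-fold and Ahrr, the AhR repressor, at least 3.17-fold. These 3 stood at 2.35 ± 0.501, 1.71 ± 0.442 and 1.58 ± 0.737 with the slide block, where they were not called (adjusted p = 0.0526, 0.0806 and 0.28). Mx1 lay lower by -2.43 ± 0.457 (adjusted p = 0.00534; with the slide block -3.26 ± 0.807, adjusted p = 0.0737), and Pfkp, a glycolytic kinase, fell by 0.85 ± 0.125 (adjusted p = 0.00183, with the slide block 0.0448). The differentiation inhibitor Id3 passed at 1.91 ± 0.602 (adjusted p = 0.042) but turned to -0.57 with the slide block, and its call ended without any 1 of the 6 arrays (adjusted p up to 0.123 without DMSO 3).

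For 1-naphthol 9 lists were called against DMSO, and 0 remained with an estimated correlation. NRF2 targets had 16 up and 1 down of 39 (18 and 2 over the list alone; adjusted p = 3.66e-06, and adjusted p = 0.116 with an estimated correlation), and AhR targets 6 up and 0 down of 9 (6 and 1 over the list alone; adjusted p = 3.14e-05, and adjusted p = 0.0518 with an estimated correlation). CAR and PXR targets had 11 up and 0 down of 24 (12 and 2 over the list alone; adjusted p = 3.14e-05, and adjusted p = 0.22 with an estimated correlation). With the slide block these 3 lists stood at adjusted p = 3.63e-07, 2.54e-05 and 0.00018. ER chaperones had 9 up and 0 down of 25 (9 and 1 over the list alone; adjusted p = 0.0135, with the slide block 4.95e-05, and adjusted p = 0.534 with an estimated correlation), and without 1-naphthol 1 the list was at 0.0526. The ER stress protein Herpud1 rose by 0.45 ± 0.055 and Syvn1 by 0.38 ± 0.0427, both also called with the slide block (adjusted p = 0.00437 and 0.024). Bile acid genes had 4 up and 2 down of 23 (5 and 2 over the list alone; adjusted p = 0.0126, with the slide block 0.000105, and adjusted p = 0.534 with an estimated correlation), among them the bile acid receptor Nr1h4 at 0.31 ± 0.0477 and the conjugating enzyme Baat at 0.21 ± 0.0408 (with the slide block 0.21 and 0.31, adjusted p = 0.197 and 0.0528).

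Downward lists with 1-naphthol began with cholesterol synthesis, 0 up and 10 down of 25 (0 and 12 over the list alone; adjusted p = 0.00191, with the slide block 0.148, and adjusted p = 0.534 with an estimated correlation). Acat2 and Cyp51 fell by 0.29 ± 0.0412 and 0.41 ± 0.0531 (with the slide block -0.27 and -0.31, adjusted p = 0.0927 and 0.113). Hypoxia genes had 1 up and 7 down of 22 (1 and 8 over the list alone; adjusted p = 0.00462, with the slide block 0.12, and adjusted p = 0.116 with an estimated correlation), with P4ha2 at -0.31 ± 0.0388 without the slide block. Immediate early genes had 2 up and 8 down of 21 (3 and 10 over the list alone; adjusted p = 0.0135, with the slide block 0.0158, and adjusted p = 0.534 with an estimated correlation), with Btg2 at -0.37 ± 0.0536 and Klf10 at -0.52 ± 0.0529, neither called with the slide block. Oxidative phosphorylation had 1 up and 7 down of 43 (1 and 7 over the list alone; adjusted p = 0.0244, with the slide block 0.0403, and adjusted p = 0.601 with an estimated correlation), and its call ended without DMSO 1 (0.156) or 1-naphthol 2 (0.0635). Cytochrome c (Cycs) fell by 0.20 ± 0.0431, and with the slide block was at -0.21 (adjusted p = 0.179). With the slide block, phase II conjugation and hepatocyte function were also called (adjusted p = 0.0268 and 0.0389, against 0.054 and 0.633 without it).

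Key genes with 1-naphthol numbered 5 up, 2 down and 12 not passed of 19, with changes of -0.26 to 0.1 among the last. Besides Nqo1 and Cyp1a1, the genes Cyp1a2 (0.37 ± 0.0631), Mt1 (0.21 ± 0.0387) and Gdf15 (0.47 ± 0.119) rose, while Hmox1 (-0.26 ± 0.0687) and Atf3 (-0.27 ± 0.0823) fell. The slide block kept the calls of Nqo1 and Cyp1a1 and none of these 5, which stood at 0.25, 0.19, 0.39, -0.22 and -0.45 with it (adjusted p = 0.25, 0.183, 0.381, 0.381 and 0.125). Leaving out 1 array ended the calls of Gdf15 (without DMSO 2 0.054, DMSO 3 0.0567, 1-naphthol 3 0.0739), Hmox1 (without DMSO 2 0.0607, DMSO 3 0.0773, 1-naphthol 2 0.0797, 1-naphthol 3 0.0653) and Atf3 (without DMSO 2 0.101, DMSO 3 0.138, 1-naphthol 1 0.0549, 1-naphthol 2 0.131, 1-naphthol 3 0.0694). In all, 2025 genes rose and 2103 fell without the slide block (173 by 2-fold or more), and 223 genes were called with it, 172 of them shared in direction. Leaving out 1 array left 1987 genes (without 1-naphthol 3) to 3107 (without DMSO 1).

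Naphthalene, which carries no hydroxyl group, moved 0 of 9 AhR targets past the threshold. Cyp1a1 was at 0.21 (95% confidence interval -0.05 to 0.48, adjusted p = 0.209) and Nqo1 at 0.06 (-0.07 to 0.19, adjusted p = 0.448). Aldh3a1 was well above background on none of the DMSO arrays and on 1 naphthalene array. Hmox1 fell by 0.41 ± 0.0687 (adjusted p = 0.0032), whereas Gdf15 rose by 0.56 ± 0.119 (adjusted p = 0.00792) and the cell cycle inhibitor Cdkn1a by 0.21 ± 0.0352 (adjusted p = 0.00342). The largest falls among the named genes were in interferon-responsive genes: Ifit3 by 3.25 ± 0.84, Oasl at least 5.97-fold, Mx1 by 2.30 ± 0.457 and Trim30d at least 4.77-fold (adjusted p = 0.0173, 0.0132, 0.00589 and 0.012). The Ifit3 call ended without DMSO 2 (0.0609), DMSO 3 (0.0687) or naphthalene 1 (0.0679), and those of Oasl and Trim30d without DMSO 3 (0.0512 and 0.0506). With the slide block these 4 lay further down, at -3.81 ± 1.57, -3.32 ± 1.14, -3.13 ± 0.807 and -3.21 ± 0.938, but were not called under its wider errors (adjusted p = 0.213, 0.143, 0.0775 and 0.103). The acetylcholine esterase gene Ache rose at least 2.96-fold (1.92 ± 0.328, adjusted p = 0.00341; with the slide block 1.90 ± 0.617, adjusted p = 0.126). Id3 and the copper transporter gene Slc31a1 passed at 2.09 ± 0.602 and 1.20 ± 0.326 but turned to -0.40 and -0.44 with the slide block. Their calls also ended without single arrays, Id3 without DMSO 1 (0.0687), DMSO 3 (0.0847), naphthalene 1 (0.0586) or naphthalene 2 (0.0739), and Slc31a1 without DMSO 3 (0.0725) or naphthalene 2 (0.0575).

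Proteasome subunits led the 5 lists called with naphthalene, all downward and none with an estimated correlation. Of 32 subunits, 0 rose and 15 fell (0 and 17 over the list alone; adjusted p = 1.56e-05, with the slide block 0.000473, and adjusted p = 0.365 with an estimated correlation), with Psmd14 at -0.30 ± 0.053 and Psmd7 at -0.38 ± 0.0616. Oxidative phosphorylation had 1 up and 9 down of 43 (1 and 9 over the list alone; adjusted p = 0.0147, with the slide block 0.0216, and adjusted p = 0.94 with an estimated correlation), with Cycs at -0.21 ± 0.0431. Cox7c, of the same list, passed at 0.82 ± 0.219 but turned to -0.26 with the slide block, and its call ended without DMSO 3 (0.0701) or naphthalene 2 (0.0545). Heat shock genes had 1 up and 8 down of 19 (1 and 8 over the list alone; adjusted p = 0.0291, with the slide block 0.676, and adjusted p = 0.805 with an estimated correlation), with the chaperones Dnaja1 and Hspb8 at -0.39 ± 0.0559 and -0.30 ± 0.0514. PPAR-alpha targets had 4 up and 7 down of 36 (4 and 12 over the list alone; adjusted p = 0.0319, with the slide block 0.92, and adjusted p = 0.923 with an estimated correlation). Ppara rose by 0.40 ± 0.0759 and the glucose sensor Txnip by 0.46 ± 0.0793, while the fatty acid hydroxylase Cyp4a3 and the lipid droplet protein Plin2 fell by 0.31 ± 0.0716 and 0.22 ± 0.0522. Hypoxia genes had 0 up and 9 down of 22 (0 and 12 over the list alone; adjusted p = 0.0213, with the slide block 0.437, and adjusted p = 0.365 with an estimated correlation), with P4ha2 at -0.17 ± 0.0388. Without DMSO 1 the PPAR-alpha, heat shock and oxidative phosphorylation lists were at 0.108, 0.0613 and 0.0929, and without naphthalene 2 the first 2 were at 0.0845 and 0.0551. The slide block also called fatty acid synthesis upward (adjusted p = 0.0216, against 0.719 without it).

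Of the 19 key genes, 2 rose with naphthalene (Cdkn1a and Gdf15), 3 fell (Hmox1, Srxn1 at -0.25 ± 0.0799 and Atf3 at -0.27 ± 0.0823) and 14 did not pass, with changes of -0.19 to 0.21. None of the 5 was called with the slide block, where they stood at 0.22, 0.48, -0.37, -0.30 and -0.45 (adjusted p = 0.102, 0.267, 0.14, 0.294 and 0.119). The Srxn1 call ended without DMSO 2 (0.137), DMSO 3 (0.0966) or naphthalene 1, 2 or 3 (0.133, 0.0666 and 0.0566), and the Atf3 call without DMSO 2 (0.0907), DMSO 3 (0.125) or naphthalene 1, 2 or 3 (0.0861, 0.0733 and 0.051). Among the named genes the slide block called Ppara (0.63, adjusted p = 0.0424) and the efflux transporter Abcc4 (0.42, adjusted p = 0.0353, against 0.26 ± 0.0508 without it). In all, 2478 genes rose and 2502 fell without the slide block (151 by 2-fold or more), and 144 genes were called with it, 110 of them shared in direction. Leaving out 1 array left 2583 genes (without DMSO 3) to 4977 (without naphthalene 3).

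1-Naphthol and naphthalene differ by 1 hydroxyl group and lie on 1 slide, so no slide difference enters. AhR targets and part of the NRF2 targets separated them. Aldh3a1, well above background on 1 of the 3 naphthalene arrays, was higher with 1-naphthol at least 19.6-fold (adjusted p = 5.49e-10). Its measured change was 4.34 (95% confidence interval 4.11 to 4.57). Cyp1a1 was higher by 2.17 (1.91 to 2.43, adjusted p = 1.88e-06). Nqo1 was higher by 1.17 (1.04 to 1.3) and Gstp1 by 0.83 (0.74 to 0.92), each at adjusted p = 1.17e-06, and Gsta2 by 0.78 ± 0.0714 (adjusted p = 0.000217). Slc43a3 was higher by 1.72 ± 0.145, Hspb1 by 0.63 ± 0.0996, Tmem117 at least 3.93-fold and Cimap2 at least 2.68-fold. Lower with 1-naphthol were Myl2 by -1.03 ± 0.149, the microvillus protein gene Vil1 by -0.83 ± 0.0829, the transporter gene Slco3a1 by -0.74 ± 0.094 and the adhesion genes Esam and Epcam by -0.52 ± 0.0897 and -0.45 ± 0.0726. Redox genes Hmox1 (0.15, 0.00176 to 0.3), Srxn1 (0.03), Gclc (0.07) and Txnrd1 (0.17) did not pass (adjusted p = 0.273 to 0.901). Of 19 key genes Nqo1 and Cyp1a1 rose and 17 did not pass (-0.23 to 0.23). In all, 206 genes were higher and 277 lower. Slide 2 alone called 53 genes, 45 of them shared, with Aldh3a1 at adjusted p = 5.83e-05. With these 6 arrays and the 1 of 1,5-naphthalenediol the changes stayed as they were, but Hspb1 (0.0806), Cimap2 (0.109), Myl2 (0.0951), Esam (0.124), Epcam (0.11), Fkbp4 (0.0848), Dnajb9 (0.107) and Acat2 (0.134) were not called. Leaving out 1 array left 176 genes (without 1-naphthol 2) to 473 (without naphthalene 3). With normexp 27.7% of changed genes were higher, not 42.7%.

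Of the 13 lists called between 1-naphthol and naphthalene, 2 remained with an estimated correlation. These were NRF2 targets, 12 up and 0 down (19 and 0 over the list alone; adjusted p = 2.33e-15, and adjusted p = 0.00638 with an estimated correlation), and AhR targets, 4 up and 0 down (6 and 0 over the list alone; adjusted p = 8.24e-09, and adjusted p = 0.00638 with an estimated correlation). CAR and PXR targets had 6 up and 0 down, Cyp2b3 by 0.42 ± 0.0484, and ER chaperones 6 up and 0 down, Herpud1 by 0.37 ± 0.055 and Dnajb9 by 0.26 ± 0.0349. Over the list alone these were 9 and 0, and 10 and 0 (adjusted p = 7.9e-09 and 1.69e-08, and adjusted p = 0.0724 with an estimated correlation for each). Phase II conjugation had 7 up and 1 down (13 and 2 over the list alone; adjusted p = 2.17e-07, and adjusted p = 0.119 with an estimated correlation). Heat shock genes had 3 up and 0 down (10 and 2 over the list alone; adjusted p = 0.000895, and adjusted p = 0.146 with an estimated correlation), Fkbp4 by 0.25 ± 0.0425. The proteasome list was called upward with 0 genes passing singly (0 and 0 over the list alone; median 0.09, adjusted p = 3.57e-08, and adjusted p = 0.0724 with an estimated correlation). The bile acid list was also called upward with 0 passing (1 and 0 over the list alone; adjusted p = 0.000895, and adjusted p = 0.229 with an estimated correlation). Downward lists were cholesterol synthesis (0 up, 1 down, the 1 being Acat2 at -0.23 ± 0.0412; 0 and 2 over the list alone), fatty acid synthesis (0 and 4; 1 and 6 over the list alone), acute phase genes (0 and 2; 3 and 7 over the list alone), immediate early genes (0 and 1; 0 and 5 over the list alone) and stellate cell markers (0 and 0; 0 and 1 over the list alone). Their tests were at adjusted p = 0.00135, 0.00465, 0.0381, 0.00109 and 0.00306, and at adjusted p = 0.256, 0.31, 0.31, 0.221 and 0.159 with an estimated correlation. Acat2 lost its call without 1-naphthol 1 (0.0685) or 2 (0.0611). Fatty acid synthesis lost its call without 1-naphthol 1 (0.0683), and the acute phase list without 1-naphthol 1 (0.0931), naphthalene 2 (0.134) or naphthalene 3 (0.181).

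The 2 diols differ only in where their hydroxyl groups sit. Against 2,7-naphthalenediol, 1,5-naphthalenediol had higher Aldh3a1 by 1.49 (95% confidence interval 1.26 to 1.72, adjusted p = 6.7e-06), Cyp1a1 by 1.61 (1.35 to 1.87, adjusted p = 9.6e-06), Nqo1 by 1.22 (1.09 to 1.35, adjusted p = 2.28e-07) and Gstp1 by 1.94 (1.85 to 2.03, adjusted p = 1.23e-10). Hspb1 was higher by 2.43 ± 0.0996, Akr1b8 by 1.48 ± 0.0474, Gsta2 by 1.13 ± 0.0714 and Alas1 by 0.99 ± 0.0653. Coro1a was at least 6.58-fold higher, Cimap2 at least 7.78-fold, Prkar2b at least 5.77-fold and the mitochondrial gene Mgarp at least 2.97-fold. Lower were Myl2 by -1.66 ± 0.149, the tubulin-binding Tppp3 at least 3.56-fold, Mybpc3 at least 3.18-fold and Cytl1 at least 2.25-fold. The stress gene Hmox1 was lower by -0.25 ± 0.0687 with 1,5-naphthalenediol (adjusted p = 0.0287; with the slide block -0.24, adjusted p = 0.0789), Gdf15 by -0.45 ± 0.119 and Trib3 by -0.38 ± 0.0757. The Hmox1 call ended without 2,7-naphthalenediol 1 (0.0711) or 3 (0.103) or 1,5-naphthalenediol 2 (0.0852) or 3 (0.0789), and the Gdf15 call without 2,7-naphthalenediol 1 (0.0563) or 1,5-naphthalenediol 1 (0.0717) or 2 (0.0518). Cyp1a2 did not pass, at -0.19 (-0.33 to -0.05, adjusted p = 0.0644). In all, 1310 genes were higher and 1604 lower, 1950 of these 2914 also called with the slide block, and slide 1 alone called 1593, with 1417 shared.

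Between the diols 15 lists were called, and 0 remained with an estimated correlation (lowest adjusted p = 0.0804). The list of immediate early genes was called downward with 1,5-naphthalenediol, 0 up and 13 down (0 and 17 over the list alone; adjusted p = 3.02e-10), with Junb at -0.61 ± 0.0689, Atf3 at -0.60 ± 0.0823 and Klf10 at -0.56 ± 0.0529. ATF4 targets had 0 up and 18 down (2 and 21 over the list alone; adjusted p = 9.52e-09), with Asns at -0.27 ± 0.0335, and cholesterol synthesis 1 up and 10 down (1 and 12 over the list alone; adjusted p = 0.000619), with Fdps at -0.31 ± 0.0405 and Sqle at -0.28 ± 0.0376. Proteasome subunits had 14 up and 0 down (17 and 0 over the list alone; adjusted p = 8.8e-09), Psmb3 by 0.38 ± 0.048. NRF2 targets had 20 up and 6 down (24 and 7 over the list alone; adjusted p = 5.23e-08), Hmox1 among the 6, and AhR targets 5 up and 0 down (5 and 1 over the list alone; adjusted p = 0.00797). CAR and PXR targets (13 up, 1 down), heat shock genes (9 and 3), phase II conjugation (9 and 1) and metal response (4 and 0) were called upward at adjusted p = 8.24e-07, 0.000402, 0.000326 and 0.0244 (over the list alone 14 and 1, 11 and 4, 9 and 2, and 4 and 0). The p53 list was called downward, with 0 of 26 up and 5 down (2 and 6 over the list alone; adjusted p = 0.016). PPAR-alpha targets (4 and 8), fatty acid synthesis (2 and 11) and acute phase genes (2 and 6) were called downward without the slide block (adjusted p = 0.0388, 0.015 and 0.0388). They were not called with it, the same fit as leaving out 1,5-naphthalenediol 3 (0.185, 0.0859 and 0.0859). Over the list alone their counts were 5 and 9, 3 and 12, and 3 and 9. The PPAR-alpha call also ended without 2,7-naphthalenediol 1 (0.0811) or 2 (0.0628), and the acute phase call without 2,7-naphthalenediol 2 (0.0725) or 1,5-naphthalenediol 1 (0.105). Cell cycle genes had 8 up and 4 down (12 and 5 over the list alone; adjusted p = 0.0388), and that call ended without 2,7-naphthalenediol 1 (0.109) or 2 (0.114) or 1,5-naphthalenediol 1 (0.0661) or 2 (0.0565). The metal response call ended without 2,7-naphthalenediol 1 (0.0567).

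1,5-Naphthalenediol carries 1 hydroxyl group more than 1-naphthol and shared slide 2 with it through 1 array. Hspb1 was higher with the diol by 1.92 ± 0.0996, Gstp1 by 1.36 ± 0.0423, the ubiquitin hydrolase Uchl1 by 1.58 ± 0.0553 and Akr1b8 by 1.19 ± 0.0474 (adjusted p = 5.5e-07, 9.93e-09, 1.07e-08 and 4.09e-08, with the slide block 8e-05, 1.99e-06, 3.43e-06 and 1.08e-05). Coro1a and the actin-binding Xirp2 were at least 6.1-fold and 4.67-fold higher. Aldh3a1 was lower with the diol by -0.67 (95% confidence interval -0.9 to -0.44, adjusted p = 0.00292, with the slide block 0.0109), Slc43a3 by -1.43 ± 0.145, and Nqo1 was higher by 0.39 (0.26 to 0.52, adjusted p = 0.00235). Cyp1a1 did not differ past the threshold, at -0.16 (-0.43 to 0.1, adjusted p = 0.414). Cell cycle genes had 15 up and 0 down (18 and 0 over the list alone; adjusted p = 6.56e-10), with the kinase Cdk1 at 0.57 ± 0.0731 and the cyclin Ccne1 at 0.41 ± 0.0524. Heat shock genes had 9 up and 1 down (12 and 1 over the list alone; adjusted p = 2e-08), proteasome subunits 8 and 0 (13 and 0; adjusted p = 7.06e-09) with Psmd14 at 0.41 ± 0.053, and NRF2 targets 12 and 2 (16 and 4; adjusted p = 3.52e-07). ATF4 targets had 1 up and 9 down (1 and 14 over the list alone; adjusted p = 0.000312), with Fgf21 at -0.50 ± 0.0619, and cholesterol synthesis 0 and 10 (1 and 11; adjusted p = 0.000597), with Fdps at -0.32 ± 0.0405 and Idi1 at -0.40 ± 0.0551. Of these 6 lists 0 remained with an estimated correlation (lowest adjusted p = 0.0799), and the AhR targets were not called (1 up, 2 down, adjusted p = 0.425). The cholesterol call ended without 1,5-naphthalenediol 3 (0.0564). In all, 863 genes were higher and 951 lower, 319 of these 1814 also called with the slide block and 13 on slide 2 alone, where the diol has 1 array and the spread comes from the other groups. The count ranged from 694 (without 1-naphthol 3) to 3409 (without 1,5-naphthalenediol 3) when 1 array was left out.

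Against naphthalene, 1,5-naphthalenediol with its 2 added hydroxyl groups had higher Aldh3a1 (at least 12.3-fold), Hspb1 by 2.55 ± 0.0996, Gstp1 by 2.19 ± 0.0423, Cyp1a1 by 2.01 ± 0.121, Akr1b8 by 1.74 ± 0.0474 and Nqo1 by 1.56 ± 0.0595, all 6 also called with the slide block. Hmox1 was higher by 0.58 ± 0.0687 (adjusted p = 0.000166, with the slide block 0.00753). Cimap2, Coro1a and Xirp2 were at least 8.15-fold, 5.98-fold and 4.26-fold higher. Cytl1 was at least 3.22-fold lower, Mybpc3 at least 3.01-fold lower and Myl2 lower by -1.84 ± 0.149. Proteasome subunits had 21 up and 0 down (24 and 0 over the list alone; adjusted p = 2.3e-13, and adjusted p = 0.0281 with an estimated correlation), with Psmd14 at 0.57 ± 0.053 and Psmd12 at 0.34 ± 0.0363. NRF2 targets had 23 up and 2 down (26 and 2 over the list alone; adjusted p = 9.84e-14, and adjusted p = 0.0193 with an estimated correlation) and heat shock genes 11 and 1 (12 and 1; adjusted p = 2.71e-08, and adjusted p = 0.0281 with an estimated correlation), with the cochaperone Cacybp at 0.56 ± 0.0518. The other 8 lists called had no call with an estimated correlation (lowest adjusted p = 0.0599). Upward they were AhR (5 up, 1 down), CAR and PXR (9 and 0), ER chaperones (8 and 1), metal response (5 and 0), phase II conjugation (13 and 3) and cell cycle (15 and 0), at adjusted p = 0.00106, 7.97e-06, 0.00305, 0.0194, 0.000251 and 7.97e-06. ER chaperones and metal response were not called with the slide block (0.0895 and 0.0527). Downward were cholesterol synthesis (2 up, 15 down, adjusted p = 3.04e-05) and fatty acid synthesis (2 and 13, adjusted p = 0.00396, with Fasn at -0.69 ± 0.0825 and Acly at -0.61 ± 0.0621, not called without 1,5-naphthalenediol 3, adjusted p = 0.0622). In all, 2231 genes were higher and 2704 lower, 1470 of these 4935 also called with the slide block and 348 on slide 2 alone, where again the diol has 1 array. The share of genes higher moved from 45.2% to 35.3% with the normexp background. Without 1 array, 3146 (1,5-naphthalenediol 2 left out) to 5851 genes (1,5-naphthalenediol 3 left out) were called.

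No slide holds both 2,7-naphthalenediol and either 1-naphthol or naphthalene. Against naphthalene, Aldh3a1 was higher with the diol at least 4.39-fold (adjusted p = 1.85e-06, with the slide block 0.00217), and against 1-naphthol it was lower by -2.16 ± 0.105 (adjusted p = 2.14e-06, with the slide block 0.000311). Cyp1a1, Nqo1 and Gstp1 were lower than with 1-naphthol by -1.77 ± 0.121, -0.83 ± 0.0595 and -0.57 ± 0.0423, and these calls held with the slide block (adjusted p = 0.0411, 0.0418 and 0.0248). Against naphthalene, Nqo1 was higher by 0.34 ± 0.0595 and Hmox1 by 0.83 ± 0.0687, and with the slide block they stood at 0.39 ± 0.109 and 0.79 ± 0.128, not called under its wider errors (adjusted p = 0.342 and 0.141). Egr1 was higher than with 1-naphthol by 1.73 ± 0.154 and than with naphthalene by 1.27 ± 0.154 (with the slide block 1.63 and 1.18, each ± 0.287, not called at adjusted p = 0.0981 and 0.298). Its list of immediate early genes was called upward in both comparisons, 15 up and 0 down against 1-naphthol (adjusted p = 1.37e-11, with the slide block 2.51e-14, and adjusted p = 0.0606 with an estimated correlation) and 13 up and 3 down against naphthalene (adjusted p = 2.13e-06, with the slide block 1.15e-07, and adjusted p = 0.149 with an estimated correlation). In all, 12 lists were called against 1-naphthol and 9 against naphthalene, 0 of them with an estimated correlation. The NRF2 list was called downward against 1-naphthol (3 up, 12 down, adjusted p = 0.0207) and upward against naphthalene (14 up, 0 down, adjusted p = 2.01e-05). The AhR list was called downward against 1-naphthol (1 up, 4 down, adjusted p = 0.000207, and adjusted p = 0.0606 with an estimated correlation) and upward against naphthalene (3 up, 0 down, adjusted p = 0.00881, and adjusted p = 0.149 with an estimated correlation). Of 2916 genes called against 1-naphthol 13 were shared with the slide block, and of 3133 against naphthalene 3.

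Some fixed lists were called against DMSO for some compounds and not for others. With 2,7-naphthalenediol the CAR and PXR (2 up, 1 down), PPAR-alpha (2 and 3), ATF4 (5 and 1), heat shock (2 and 1), metal response (1 and 0), proteasome (0 and 3), phase II conjugation (2 and 3), fatty acid synthesis (1 and 3), bile acid (0 and 1) and hypoxia (2 and 1) lists were at adjusted p = 0.0941 to 0.76. With 1,5-naphthalenediol, ER chaperones (7 up, 2 down, adjusted p = 0.0847), bile acid genes (5 and 4, 0.171) and immediate early genes (2 and 7, 0.124) were not called, and the first 2 were with the slide block (0.0105 and 0.0416). With 1-naphthol, PPAR-alpha targets (1 up, 7 down), ATF4 targets (4 and 6), heat shock genes (3 and 3), metal response (4 and 0), proteasome subunits (0 and 3), phase II conjugation (10 and 3), fatty acid synthesis (3 and 4) and cell cycle genes (3 and 3) were at 0.054 to 0.914. For the heat shock list the median was 0.02 and the mean -0.0025. With naphthalene, NRF2 targets (3 up, 2 down, adjusted p = 0.718), AhR targets (0 and 0, 0.84), CAR and PXR targets (3 and 2, 0.658) and ATF4 targets (3 and 7, 0.104) did not pass. ER chaperones (2 and 7), phase II conjugation (1 and 4), cholesterol synthesis (1 and 7), bile acid genes (1 and 2), metal response (1 and 1), cell cycle (2 and 3), fatty acid synthesis (4 and 2) and immediate early genes (4 and 7) were at 0.302 to 0.787 with naphthalene.

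Lists of p53 targets, hepatocyte function, acute phase genes and markers of other cell types were called against DMSO for none of the 4 compounds without the slide block. In the order the 2,7- and 1,5-diols, 1-naphthol and naphthalene, p53 targets were at adjusted p = 0.152, 0.755, 0.509 and 0.924, with 4, 1, 4 and 7 of 26 up and 2, 6, 5 and 7 down. Hepatocyte function genes were at 0.535, 0.853, 0.633 and 0.413, with 2, 9, 6 and 3 of 43 up and 3, 7, 1 and 7 down. Its albumin gene Alb did not pass with any compound (-0.09, -0.09, -0.09 and -0.01). Acute phase genes were at 0.339, 0.171, 0.124 and 0.921, with 4, 3, 1 and 3 of 22 up and 1, 8, 3 and 2 down. Markers of stellate cells (11 genes) were at 0.929, 0.485, 0.307 and 0.678, of macrophages (7 genes) at 0.926, 0.525, 0.249 and 0.939, of endothelial cells (7 genes) at 0.547, 0.635, 0.914 and 0.413, and of bile duct cells (5 genes) at 0.24, 0.184, 0.322 and 0.939. Epcam, a bile duct marker, fell by 0.44 ± 0.0726, 0.32 ± 0.0726 and 0.50 ± 0.0726 with the first 3 compounds, the last of these at -0.45 ± 0.135 with the slide block and not called there (adjusted p = 0.11). Median, mean and test differed in sign for acute phase genes (median -0.0044, mean 0.06), stellate markers (-0.06 and 0.00728, test down) and macrophage markers (-0.04 and -0.03, test up) with 2,7-naphthalenediol. The same held for hepatocyte function with 1,5-naphthalenediol (-0.03 and 0.02, test down), endothelial markers with 1-naphthol (-0.02 and 0.03, test down) and macrophage markers with naphthalene (-0.01 and -0.007, test up). Of 20 lymphocyte markers 2 could be tested, Cd3d and Nkg7, too few for a list test. Cd3d fell by 0.38 with 2,7-naphthalenediol (adjusted p = 0.0373) and Nkg7 was at 0.20 (adjusted p = 0.629), and neither was called with the other 3 compounds.

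Profiles against DMSO were compared across all 19803 genes, which are not independent replicates. 1-Naphthol and naphthalene had the highest correlation of the 6 pairs, r = 0.812 (covariance 0.0617) and 1339 genes up and 1239 down in both, against 253 and 266 if the calls were independent. 1,5-Naphthalenediol and 1-naphthol followed at r = 0.662 (covariance 0.0501), with 807 up and 1226 down in both (191 and 268 if independent). The remaining pairs were the diols at 0.552 (0.0327; 585 and 532 shared, against 116 and 122), 1,5-naphthalenediol and naphthalene at 0.503 (0.037; 647 and 899, against 233 and 319), 2,7-naphthalenediol and 1-naphthol at 0.482 (0.0295; 556 and 499, against 126 and 102) and 2,7-naphthalenediol and naphthalene at 0.472 (0.0281; 700 and 481, against 154 and 121). Simulated profiles with no compound effect that share 3 controls gave r = 0.501, a covariance of 0.00886 and an overlap of 0.00667 genes on average. The 3 controls are too few to give each compound 2 of its own, so part of the excess may come from them. Those simulations hold no slide difference, and 1-naphthol and naphthalene share a slide apart from DMSO. With a slide difference and no compound effect, simulated profiles of this pair gave r = 0.847, a covariance of 0.0444 and 4180 shared genes, so its correlation and overlap do not exceed what a slide difference of that size gives, while its observed covariance of 0.0617 lies above it. For 1-naphthol or naphthalene with 1,5-naphthalenediol these simulations gave r = 0.62 and 0.621 (covariance 0.0201 and 0.0202), and with 2,7-naphthalenediol 0.276 and 0.278 (0.00803 and 0.00807). The diols stood at 0.446 (0.00802). With the slide block the observed r of 1-naphthol and naphthalene was 0.86, beside 0.847 in simulations fitted the same way. In that model 1,5-naphthalenediol stood at 0.749 with 1-naphthol and 0.622 with naphthalene (simulated 0.62 and 0.621). The r of 2,7-naphthalenediol was 0.591 with the other diol, 0.618 with 1-naphthol and 0.612 with naphthalene (simulated 0.445, 0.275 and 0.276).

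**Figure D1:**
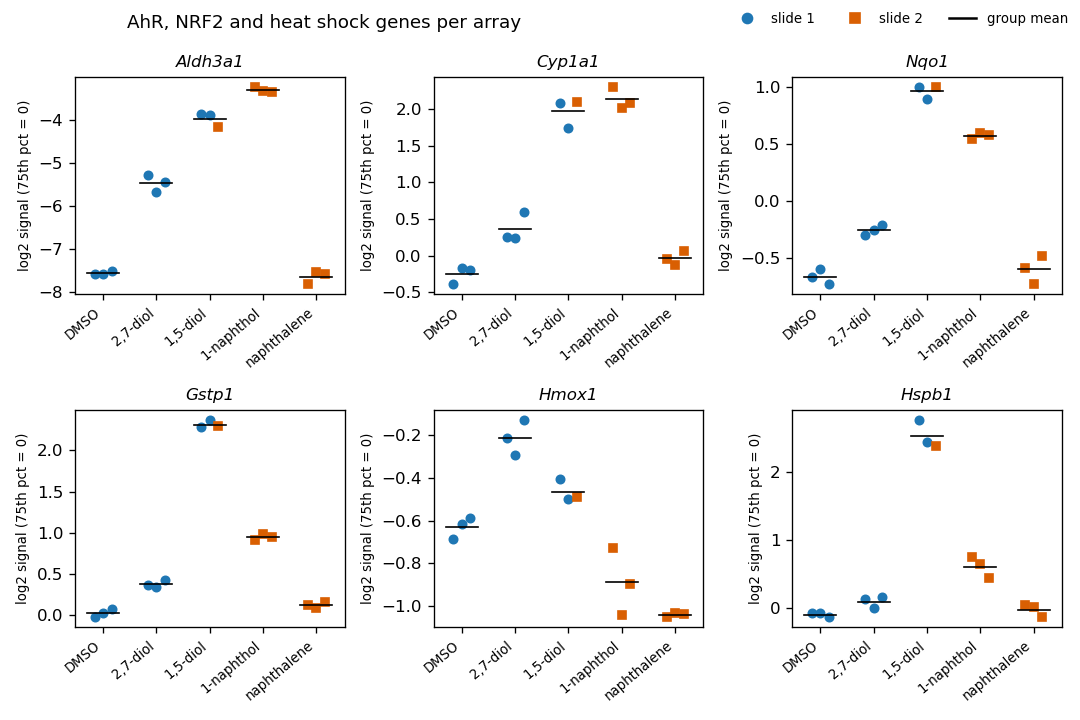
Signal of Aldh3a1, Cyp1a1, Nqo1, Gstp1, Hmox1 and Hspb1 on each of the 15 arrays (log2, with the array's 75th percentile at 0; circles slide 1, squares slide 2, lines group means). Nqo1 lay at 0.9 to 1 with 1,5-naphthalenediol and at -0.72 to -0.48 with naphthalene.

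**Figure D2:**
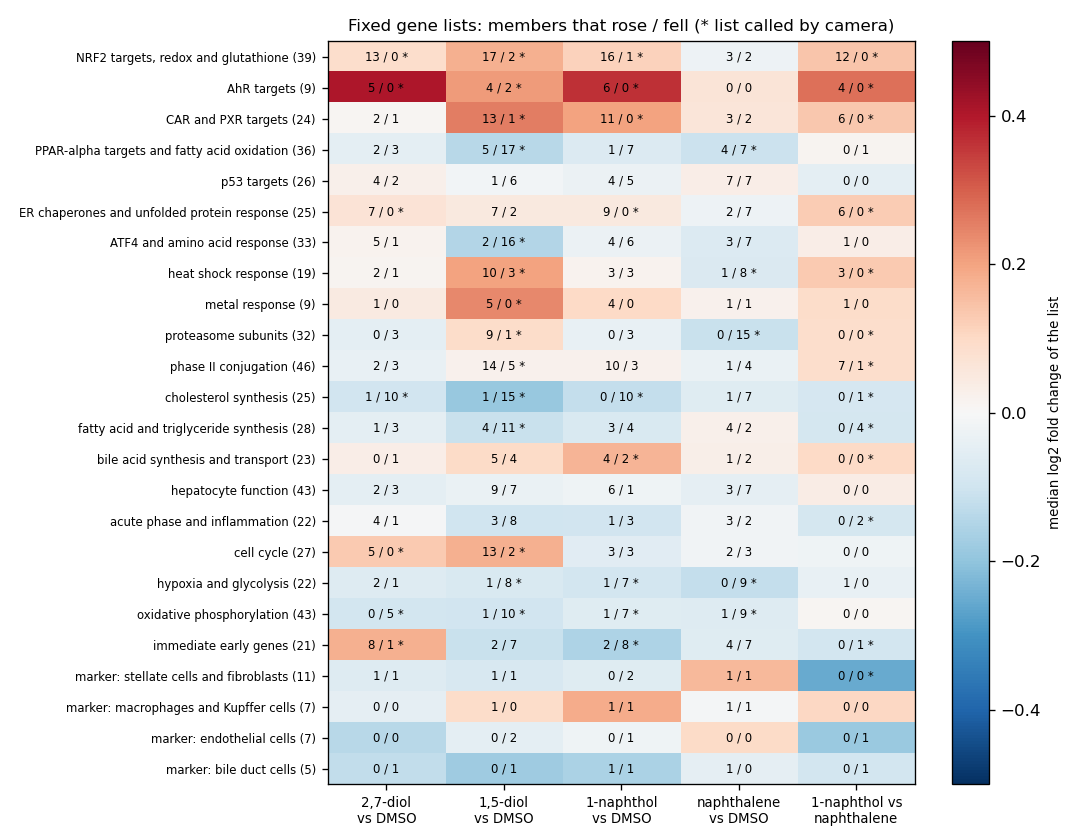
Median log2 change of the 24 tested gene lists (color) in 5 comparisons, with the number of genes that rose and fell and an asterisk where the list was called. AhR targets had 5, 4, 6 and 0 genes up with the 2,7- and 1,5-diols, 1-naphthol and naphthalene against DMSO, and 4 with 1-naphthol against naphthalene.

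**Figure D3:**
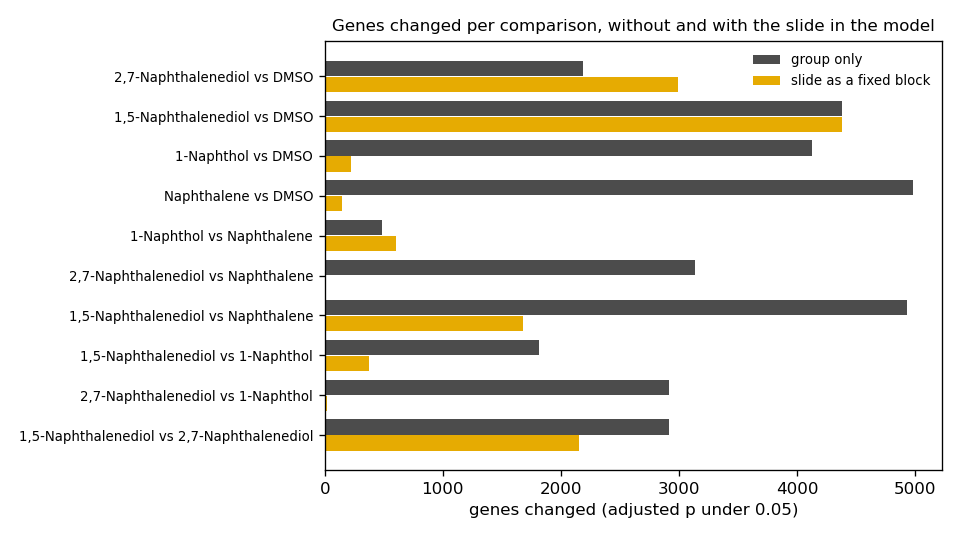
Number of genes changed in each of the 10 comparisons without and with the slide block. Naphthalene against DMSO had 4980 and 144 genes, and 1-naphthol against naphthalene 483 and 605.

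**Figure D4:**
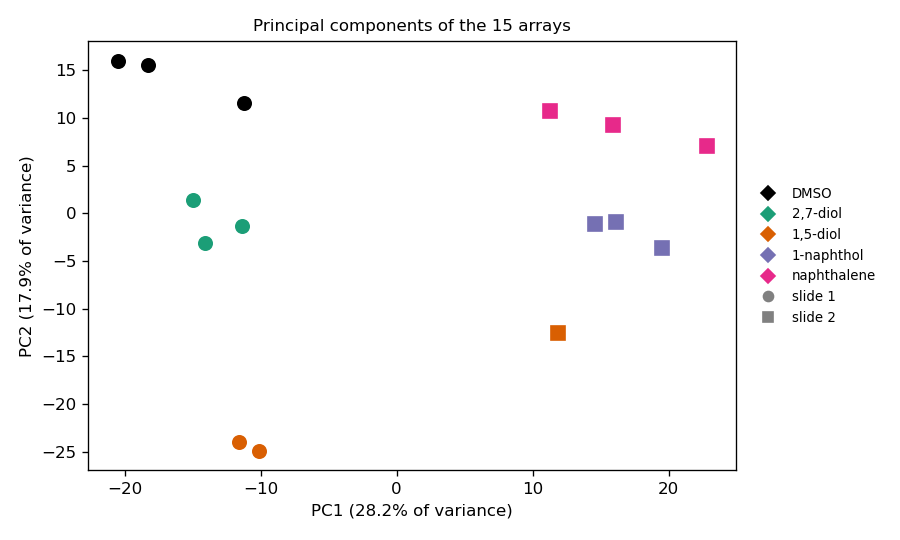
The 15 arrays on the first 2 principal components (28.2% and 17.9% of the variance), colored by group and shaped by slide. Slide 1 arrays lay at -20.5 to -10.1 on the first component and slide 2 arrays at 11.3 to 22.8.

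**Figure D5:**
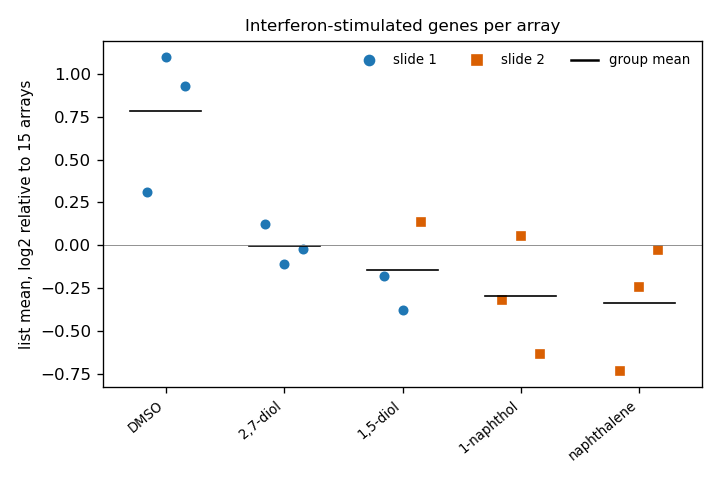
Mean of 43 interferon-stimulated genes on each array (log2, relative to the mean of all 15 arrays), by group and slide. DMSO 1, 2 and 3 were at 0.31, 1.1 and 0.93.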

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

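The alternative without DMSO 2 and DMSO 3 and the leave-one-out values of the profile similarities were chosen after results had been seen, and the other alternatives before. Counts of genes below follow the order the 2,7- and 1,5-diols, 1-naphthol and naphthalene against DMSO, then 1-naphthol against naphthalene, 2,7-naphthalenediol, 1,5-naphthalenediol against naphthalene, 1,5-naphthalenediol, 2,7-naphthalenediol against 1-naphthol, and 1,5-naphthalenediol against 2,7-naphthalenediol. Reported counts were 2186, 4386, 4128, 4980, 483, 3133, 4935, 1814, 2916 and 2914, and 8852 for the F test. A count is called moved when it left 1.5 times the reported one either way, and alternatives not given for a count left it within that range.

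Without a filter on dim probes, which adds probes near background to the adjustment, counts were 519, 2422, 1966, 2181, 142, 1022, 2527, 572, 1186 and 1375, and 4715 for the F test. With only the arrays of the groups compared, which leaves fewer arrays for the spread, the moved counts were 1031, 2362, 2795 (naphthalene against DMSO), 53, 1856, 1186, 447 and 1136 (1,5-naphthalenediol against 2,7-naphthalenediol). The arrays of 1 slide, fewer again, moved 1-naphthol against naphthalene to 53, 1,5-naphthalenediol against naphthalene to 380, against 1-naphthol to 15 and against 2,7-naphthalenediol to 1593. 1-Naphthol against naphthalene moved up with normexp (801) and with trend and robust moderation (848), and the cause was not tested. Without DMSO 2 and 3, DMSO 1 stood alone and was assumed to vary like the other groups, and the counts against DMSO were 166, 1352, 189 and 197. Normexp and quantile scaling shifted the median of all genes by at most 0.03. The share of changed genes that were higher moved by 15 points for 1-naphthol against naphthalene, and by at most 9.9 points in the other comparisons.

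The slide as a fixed block moved the counts that lie across slides, to 223 for 1-naphthol and 144 for naphthalene against DMSO, 4 for 2,7-naphthalenediol against naphthalene and 16 against 1-naphthol, 1677 for 1,5-naphthalenediol against naphthalene and 371 against 1-naphthol, and 5196 for the F test. As a random block (correlation 0.187) it gave 1427, 1866, 141, 241 and 897 for these pairs without 1,5-naphthalenediol against naphthalene, and 5708 for the F test.

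Together, the slide block and replicate block gave 57 and 1 against DMSO for 1-naphthol and naphthalene, 3 and 4 for 2,7-naphthalenediol against naphthalene and 1-naphthol, 1041 and 120 for 1,5-naphthalenediol against the same, 1939 between the diols and 4196 for the F test. The replicate block alone, though no pairing by replicate number was seen, moved none of the counts (1872, 4093, 3715, 4579, 412, 2791, 4641, 1527, 2585 and 2702; F test 8083).

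Leaving out 1 array gave 732 to 1614, 3002 to 4381, 1987 to 3107, 2583 to 4977, 176 to 473, 1180 to 2479, 3146 to 5851, 694 to 3409, 1180 to 1801 and 1823 to 2625 genes, and 6781 to 9311 for the F test. Without 1,5-naphthalenediol 3, its array on slide 2, 3409 genes differed from 1-naphthol and 5851 from naphthalene, above the reported counts.

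Of 96 list tests against DMSO 35 were called, 33 to 37 when 1 array was left out and 1 with an estimated correlation, which allows for genes of a list varying together. Over all 10 comparisons, 95 of 101 list calls were lost with the estimated correlation. The other alternatives without the slide lost 1 to 13 of the 101. The fixed slide block lost 16 and added 12 in the same direction, and 3 more in the opposite direction. The oxidative phosphorylation list of 2,7-naphthalenediol against 1-naphthol lost its call in quantile scaling, where its mean stayed below 0 (-0.0189) while the direction of its test turned upward (adjusted p = 0.874). The cause was not tested.

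The similarity of 2,7-naphthalenediol to 1,5-naphthalenediol, 1-naphthol and naphthalene was 0.552, 0.482 and 0.472, that of 1,5-naphthalenediol to the last 2 was 0.662 and 0.503, and that of these to each other 0.812. Without a filter the values that moved were 0.485, 0.393, 0.417, 0.573 (1,5-naphthalenediol and 1-naphthol) and 0.694 (1-naphthol and naphthalene). With the slide as a fixed block they were 0.591, 0.618, 0.612, 0.749, 0.622 and 0.86, with the slide block and replicate block 0.584, 0.592, 0.586, 0.75, 0.626 and 0.867, and with the random block 0.562, 0.555 and 0.793 for the pairs of 1-naphthol or naphthalene with 2,7-naphthalenediol and with each other. The diols moved to 0.587 with normexp, and 1-naphthol and naphthalene to 0.828 with the filter on all arrays. With 1 array left out they were 0.484 to 0.619, 0.448 to 0.572, 0.419 to 0.562, 0.525 to 0.713, 0.373 to 0.576 and 0.77 to 0.842. Causes were not tested.

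For the 290 gene results followed, 234 of them called, 4740 of 5247 values under the alternatives kept direction and side of the threshold, 465 lost their call, 31 gained one and 11 reversed. With the fixed slide block 63 lost their call and 5 reversed: Id3 to -0.57 (1-naphthol against DMSO) and -0.40 (naphthalene against DMSO), Cox7c to -0.26 in both, and Slc31a1 to -0.44 (naphthalene). In the slide block and replicate block model the same 5 stood at -0.37, -0.19, -0.34, -0.34 and -0.49. Ugt1a6 with 1,5-naphthalenediol reversed to 0.26 on the mean of its probes. The cause of these reversals was not tested. Without DMSO 2 and 3, 70 of 126 calls against DMSO were lost: 18 of 26 with 2,7-naphthalenediol, 11 of 46 with 1,5-naphthalenediol, 18 of 30 with 1-naphthol and 23 of 24 with naphthalene. Signal over background limits what can be seen of dim genes: 241 of these 290 results had a probe above background on all 15 arrays, and under that filter 0 of their 186 calls were lost.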

Other observations

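Tests of the slide, the tests of genes shared by the hydroxylated compounds, regroupings within slides, tests of the interferon-stimulated genes and their list, and estimated correlations for the shortened NRF2 list and the splits were chosen after results had been seen, while the NRF2 test without AhR genes and the other splits were set before. Genes that follow the hydroxyl groups were sought among those called against both DMSO and naphthalene, in the same direction, in all 3 hydroxylated compounds. There were 37 higher (28 with a symbol) and 20 lower (18 with a symbol). Leaving out any 1 of the 15 arrays kept 9 of the 37 and 4 of the 20. Among those kept, the smallest changes over the 6 comparisons were 0.53 for the neurofilament gene Nefl, 0.34 for Nqo1, 0.31 for the aldo-keto reductase gene Akr7a3, 0.28 for Herpud1, 0.265 for the aldehyde oxidase gene Aox1 and 0.26 for Gstp1, and on the lower side -0.64 for Fam25a and -0.46 for Vil1. Aldh3a1 was kept too, and was the 1 gene called in all 6 comparisons with the slide block. Cyp1a1 was not kept, since its call for 2,7-naphthalenediol against naphthalene (0.40, adjusted p = 0.0435) ended without any 1 of the 6 arrays (adjusted p up to 0.158 without 2,7-naphthalenediol 3).

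Of 43 interferon-stimulated genes tested against DMSO, 19 fell with 2,7-naphthalenediol, 32 with 1,5-naphthalenediol, 36 with 1-naphthol and 36 with naphthalene, and 0 rose (30, 38, 39 and 39 fell over the list alone, with 0, 1, 1 and 1 up). Mean changes were -0.785, -0.92, -1.08 and -1.12, among them the antiviral genes Mx1, Ifit3, Oasl2 (-1.36, -1.82, -2.19 and -2.31) and Rsad2 (-1.33, -1, -1.95 and -3.03). The list was written after single genes of it had been seen to fall on these arrays, so no test of it is given. In the model with the slide block the means were -0.785, -1.06, -1.49 and -1.53, and 21, 35, 2 and 1 genes fell. 1-Naphthol and naphthalene did not differ past the threshold in any of the 43 (mean 0.04).

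The 4 comparisons that lie wholly across slides called 2916 to 4980 genes, and the 2 wholly within 1 slide 2186 and 483, but 1,5-naphthalenediol against DMSO called 4381 when its array on slide 2 was left out. If the slide contributes, the difference between slides within 1,5-naphthalenediol should resemble those comparisons, and it did, with r = 0.32 for naphthalene and 0.3 for 1-naphthol against DMSO. With the slide block 2.21% of the 4980 genes called for naphthalene and 4.17% of the 4128 for 1-naphthol were called in the same direction. The sign was kept for 91.3% and 90%, while the median size went from 0.263 to 0.2 and from 0.291 to 0.223 and the median standard error from 0.0725 to 0.121, so that calls ended largely through wider errors, and slide and compound cannot be told apart for most of these genes. For AhR and NRF2 targets the whole lists, called within slide 2, argue against the slide as the whole cause. The 20 of 46 members that rose with 1-naphthol against DMSO (mean 0.81) were chosen on the same 1-naphthol arrays. Their mean over naphthalene was 0.739 (standard error 0.037), with 18 higher and 14 called.

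Candidate explanations for the lower interferon-stimulated genes are the slide, the state of 2 DMSO cultures, or fewer macrophages after exposure. The slide is argued against for 2,7-naphthalenediol, whose mean change lies within slide 1 (-0.785, standard error 0.25). For 1-naphthol and naphthalene it cannot be told apart, since the slide difference within 1,5-naphthalenediol rests on 1 array against 2 (0.415, in the direction opposite to the change). DMSO 1 stood at 0.313, above the highest array of any compound (0.134) and below DMSO 2 and 3 (1.1 and 0.931), so an unusual state of the latter cannot be told apart from an effect of the compounds with 3 DMSO arrays. Macrophage loss is argued against, since their 7 markers had a lowest mean change of -0.0276 (2,7-naphthalenediol) and a lowest 95% bound over the 4 comparisons of -0.26 (1,5-naphthalenediol, -0.26 to 0.27), above the list means of -1.12 to -0.785, although 7 of 22 markers could be tested. A fall of interferon signalling with the compounds, untested otherwise, remains a hypothesis.

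NRF2 targets could have followed from the genes they share with the AhR battery. Without Gsta2, Gsta5, Nfe2l2 and Nqo1 the remaining 35 genes kept adjusted p = 8.13e-05 with 2,7-naphthalenediol, 2.35e-09 with 1,5-naphthalenediol and 0.000285 with 1-naphthol against DMSO (0.000117, 3.4e-09 and 4.83e-05 with the slide block), with 12 up and 0 down, 14 and 2, and 12 and 1. With an estimated correlation these 35 genes stood at adjusted p = 0.2, 0.0433 and 0.182, so that 1 of the 3 calls remained. For naphthalene the list stood at 0.679 (3 up, 2 down), and between 1-naphthol and naphthalene at 2.69e-10 (8 up, 0 down; adjusted p = 0.0156 with an estimated correlation). With that correlation the whole NRF2 list stood at 0.218, 0.027 and 0.116 against DMSO.

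For the F test, 1 of 100 regroupings of the 15 arrays, the real one, gave 8852 genes or more, and the highest other gave 60. Those regroupings cross the slides. Within slides, 1 of 100 gave 8852 or more (highest other 2387). With the slide block added, 1 of 100 gave 5196 or more (highest other 320), so chance is excluded in both models. For pairs the 10 splits of 6 arrays are too few to give a share below 0.05. Mixed splits carry the real difference in their spread, so few calls are built in. Real splits of 1-naphthol or naphthalene from DMSO or 2,7-naphthalenediol are also slide splits. Real (and highest other) splits gave 2186 (2), 4386 (0), 4128 (0) and 4980 (0) genes against DMSO, in the order above. 1-Naphthol against naphthalene had 483 (1). The 2,7- and 1,5-diols had 3133 (1) and 4935 (5) against naphthalene, 2916 (0) and 1814 (0) against 1-naphthol, and 2914 (0) between them. Lists called with the preset correlation reached the real number more often. In the same order the real and highest other numbers were 7 (7, in 3 of 10 splits), 14 (7, 1 of 10), 9 (10, 2 of 10), 5 (5, 4 of 10), 13 (12, 1 of 10), 9 (9, 3 of 10), 11 (10, 1 of 10), 12 (12, 2 of 10), 6 (11, 7 of 10) and 15 (11, 1 of 10). With an estimated correlation they were 0 (0), 1 (0), 0 (0), 0 (1), 2 (0), 0 (1), 3 (0), 0 (0), 0 (0) and 0 (0).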
